A study of Mus musculus with 4 samples.

How the data were processed

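Live CD45-positive cells were sorted from enzymatically digested hearts without atria, and 3' single-cell RNA libraries were made with 10x Genomics chemistry, per the labels' protocols. There were 4 libraries, 1 each of PD1 heterozygous (Het) and homozygous (KO) deletion after sham surgery or MI. Reads were processed with Cell Ranger 6.1.1 and the data with Seurat 4, per the submitters' processing notes, while Cell Ranger 4.0.0 is named per the file headers. The builds named in the labels are mm10 and GRCm38. The deposited matrices hold raw UMI counts per gene and barcode, with no normalization by the authors, and no cell type annotation was used. The settings of cell calling are not given in the sources used here. Coordinates of Pdcd1 came from the GENCODE annotation of GRCm38.

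Cells with at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept, which left 5376, 6407, 5074 and 7104 cells in Het_sham, KO_sham, Het_MI and KO_MI. Scrublet's method was run per library. Its automatic threshold called 0, 0, 1 and 5 cells and so did not work. A score threshold at the rate expected from the number of barcodes (0.8% per 1000) was used in its place and removed 314, 366, 175 and 461 cells. Droplets with at least 3 UMIs of each of 2 out of 6 lineages, at 10% or more of the level in cells that the lineage leads, were removed as well (843, 819, 854 and 1443 droplets, or 15.7%, 12.8%, 16.8% and 20.3%). That second filter was chosen after seeing the data.

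Counts were scaled to 10000 UMIs per cell and log-transformed. Cells were clustered with the Leiden algorithm at resolution 1.0 on 15 nearest neighbours in 30 principal components of 2000 variable genes. Pdcd1, sex-linked, mitochondrial and haemoglobin genes were left out of that step. Clusters were named by the mean log2 level of 33 fixed marker lists against the mean of all clusters, with 20 CPM (UMIs per 1000000 UMIs) added, and lymphoid and dendritic cells were clustered again. A name needed a mean of at least 0.8, at least 3 detected markers, and top 10 genes that did not lead to another class. These thresholds were set after seeing the data, and left 7.36%, 7.73%, 6.69% and 8.02% of kept cells unnamed. T cell clusters with Rag1 at 50 CPM or more were set apart. The T cell cluster passed the rule, but on clustering again 20, 31, 13 and 44 of the T cells fell in a sub-cluster with T and NK genes that could not be named, since its leading genes were NK cell markers. It stayed in the class, so values without the T cells of all unnamed sub-clusters (22, 39, 22 and 52 cells) were computed as well, an alternative chosen after seeing the data. A class was compared only with at least 100 cells in both libraries, in which NK cells passed for KO_MI over Het_MI only.

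With 1 library per group there is no test across animals, so no p-value and no count of changed genes is given. Shares carry exact Clopper-Pearson intervals and counts exact Poisson intervals at 95%. UMIs were summed over the cells of a class in each library and divided by the class total as CPM, and log2 ratios carry exact conditional binomial intervals. TMM placed the centre of the log2 ratios more than 0.1 from 0 in several classes, at −0.17 in neutrophils and −0.11 in macrophages of KO_MI over KO_sham, at −0.13 in T cells and NK cells and −0.11 in macrophages and non-classical monocytes of KO_MI over Het_MI, and at −0.14 in neutrophils of Het_MI over Het_sham. Median-of-ratios factors did so for KO_MI over Het_MI in B cells (−0.107), macrophages (−0.118) and T cells (−0.101), for KO_MI over KO_sham in B cells (−0.115), macrophages (−0.128) and neutrophils (−0.137), and for Het_MI over Het_sham in neutrophils (−0.105). A count of 0 was set at 3 counts for a bound. For gene lists, the median log2 ratio over members with at least 30 UMIs was set against 10000 random lists of the same size drawn from 20 bins of expression, and needed at least 5 members. Its interval came from 200 Poisson draws. The 27 gene lists, the markers, the comparisons, the rule for named genes and the first set of alternatives were fixed before the data were examined. Of the 22 genes of the type I interferon list, 21 are in the files.

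The rule for named genes was as follows. Pdcd1 and its ligands were always named. For KO_MI over Het_MI and Het_MI over Het_sham, the 5 highest and 5 lowest genes were named in macrophages and T cells, 2 of each in monocytes and neutrophils and 1 of each in other classes. For the other contrasts and the ratio of ratios, 3 of each were named in macrophages and T cells. A gene needed at least 100 UMIs over the libraries, 50 CPM in the higher one, an interval beyond 1.5-fold (not asked of the ratio of ratios) and a level of at least 10% of the highest class. Mitochondrial, ribosomal protein, haemoglobin, sex-linked, receptor segment and unnamed gene models were left out. From each list described, up to 4 members with the most UMIs and the highest and lowest member were named. Where 1 cell held much of a gene's UMIs, the ratio without it was computed.

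The steps were tested on simulated data drawn from the Poisson law that the intervals assume. The draws hold no spread between cells, such as 1 cell with much of a gene's UMIs. How well the intervals cover such spread in the real data was therefore not tested. For macrophages of KO_MI over Het_MI, with 200 of 10463 genes changed, genes set to 0.25, 0.5, 2 and 4 times their level came back at median log2 ratios of −2.01, −1.02, 0.99 and 1.99. Intervals beyond 1.5-fold were found for 58 of 58, 35 of 44, 47 of 50 and 48 of 48 of them, and for 0 of 10263 unchanged genes. For T cells of the same contrast, over 1729 genes, these were 57 of 58, 31 of 44, 25 of 50 and 48 of 48. Of 200 unchanged lists, 10 in macrophages and 4 in T cells lay outside the central 95% of random lists.

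Alternatives covered the mitochondrial limit (5%), the UMI minimum (1000), doublets kept, resolution 0.5 and 2.0, names per cell, the denominator of shares, TMM and median-of-ratios factors, a mean over cells, thinning to 2000 UMIs per cell (which left out 528, 409, 237 and 555 shallower cells), the UMI minimum of list members (1 or 100) and the level against the highest class. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.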

Results

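Single-cell RNA was measured in live CD45-positive cells sorted from neonatal mouse hearts. CD45 marks immune cells of the blood and of tissues. The mice carried a deletion of PD1, an inhibitory receptor of activated lymphocytes encoded by Pdcd1, on 1 chromosome (Het) or on both (KO). They had a sham operation or a myocardial infarction (MI) at postnatal day 2, and the hearts were taken 7 days later. The 4 groups, Het_sham, KO_sham, Het_MI and KO_MI, hold 1 library each, so no difference reported here has a replicate check and none was tested. The libraries held 7745, 7787, 6157 and 8379 barcodes in that order, with 52701847, 66587021, 60461796 and 72002420 UMIs (unique molecular identifiers, counted RNA molecules). After filtering, 4361, 5434, 4173 and 5475 cells remained, with a median of 5690, 6613, 7626 and 6246 UMIs per cell. Of these, 3931, 4870, 3763 and 4843 cells lay in clusters that could be named as immune cells from fixed markers. Names such as macrophage stand for macrophage-like clusters. Brackets give 95% intervals, which cover counting error only. Expression is in CPM, the UMIs of a gene per 1000000 UMIs of its class in a library, and differences are log2 ratios unless a fold is named. Outside gene lists, genes called highest or lowest are so among those that met the rule for named genes.

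The deleted gene comes first, because its RNA could check the genotype labels. Pdcd1 (ENSMUSG00000026285) lies on chromosome 1 of GRCm38 from 94038305 to 94052553 on the minus strand, with 5 exons. Its 3' untranslated region, where 3' tags of this assay fall, spans 94038305 to 94039307 in exon 5. Pdcd1 RNA was not lost from the libraries labelled KO. In T cells it stood at 15.1 [8.28 to 25.4] CPM in Het_sham and 17.2 [9.42 to 28.9] in KO_sham, where 35.7% of its 14 UMIs came from 1 cell. After MI it stood at 40.2 [27.1 to 57.4] in Het_MI and 52.5 [37.0 to 72.4] in KO_MI, from 30 and 37 UMIs. The levels depend on the doublet filter, since with doublets kept these 2 values were 10.3 and 31.6 CPM, and with only Scrublet calls removed 11.2 and 35.2. Without the T cells of unnamed sub-clusters Pdcd1 stood at 47.9 CPM in Het_MI and 42.4 in KO_MI, so the order of the MI libraries is not fixed. In NK cells the KO_MI library held 107 UMIs, or 107 CPM [87.6 to 129], against 5 UMIs and 7.48 CPM [2.43 to 17.5] in Het_MI. The labels do not say which part of the gene was deleted, so a 3' tag outside that part checks nothing here, and each genotype below is that of the library label.

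Cells with a Pdcd1 UMI were most frequent in type 2 innate lymphoid cells, T cells and NK cells, and as rare in B cells as in macrophages. Among type 2 innate lymphoid cells they were 2 of 12, 9 of 29, 13 of 39 and 18 of 53 in Het_sham, KO_sham, Het_MI and KO_MI, and their share in B cells was 0.220%, 0.186%, 0.265% and 0.141%. In T cells their share was 5.44% [2.38 to 10.4], 4.73% [1.92 to 9.50], 10.9% [6.11 to 17.7] and 18.5% [12.4 to 26.1] in the same order, at median depths between 4775 and 5477 UMIs per cell. With every cell thinned to 2000 UMIs the shares were 1.39%, 2.76%, 6.35% and 11.4%. Among macrophages the share was 0.325% in Het_MI and 0.218% in KO_MI, at median depths of 10073 and 8085 UMIs. In the sham libraries 0 of 1096 and 0 of 2080 macrophages held a Pdcd1 UMI, which allows up to 0.274% and 0.144%. No neutrophil held a Pdcd1 UMI in any library. The ligand PD-L1, encoded by Cd274, had its highest level in non-classical monocytes, at 183, 167, 179 and 118 CPM in the same order. There it was level between Het_MI and Het_sham (−0.03) and lower in KO_MI than in Het_MI (−0.60) and KO_sham (−0.499). In macrophages it was counted at 2.99, 3.97, 7.05 and 10.2 CPM. Pdcd1lg2, which encodes the other ligand PD-L2, was counted in macrophages with 8 UMIs in Het_MI and 38 in KO_MI, a log2 ratio of 2.28 [1.16 to 3.59].

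**Figure D1:**
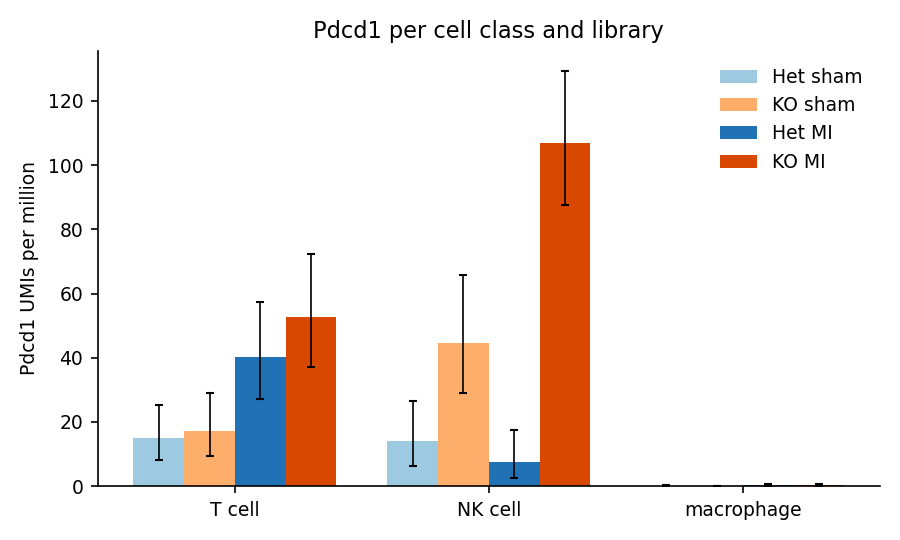
Pdcd1 in T cells, NK cells and macrophages of each library, as CPM of the class with exact Poisson 95% intervals (counting error only, 1 library per group). Other classes are not drawn. T cells of KO_MI stand at 52.5 and those of Het_MI at 40.2, so the library labelled KO did not lose the tag.

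The first comparison asks what loss of PD1 does to the immune cells of the infarcted heart. Between KO_MI and Het_MI, the macrophage share was nearly equal, while both monocyte classes were larger and B cells smaller in KO_MI. KO_MI macrophages carried more RNA of interferon-induced genes and of MHC class II, the molecules that present antigen to CD4 T cells. They carried less RNA of the resident macrophage programme. The T cell class of KO_MI had more cytotoxic and less naive and type 17 RNA, partly through another mix of sub-clusters.

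Macrophages made up 47.3% of named immune cells in KO_MI and 49.0% in Het_MI, a ratio of 0.965 [0.907 to 1.03]. Classical monocytes, the blood-derived precursors of recruited macrophages, made up 9.37% and 5.87%, a ratio of 1.60 [1.36 to 1.88]. Non-classical monocytes, which patrol vessels, made up 7.04% and 4.89%, a ratio of 1.44 [1.20 to 1.73]. B cells made up 14.7% and 20.0%, a ratio of 0.732 [0.659 to 0.812]. Mast cells made up 0.372% and 1.09%, a ratio of 0.341 [0.184 to 0.607]. NK cells had a ratio of 1.21 [0.945 to 1.55] and T cells one of 0.819 [0.639 to 1.05], so neither interval excluded 1. The T cell ratio depends on the processing, at 0.611 without the T cells of sub-clusters that could not be named and 1.05 with only Scrublet calls removed. A cluster group of T cells with Rag1, set apart because Rag1 belongs to developing lymphocytes, made up 4.17% and 2.29%, a ratio of 1.83 [1.41 to 2.38]. Neutrophils made up 6.26% and 6.01%.

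**Figure D2:**
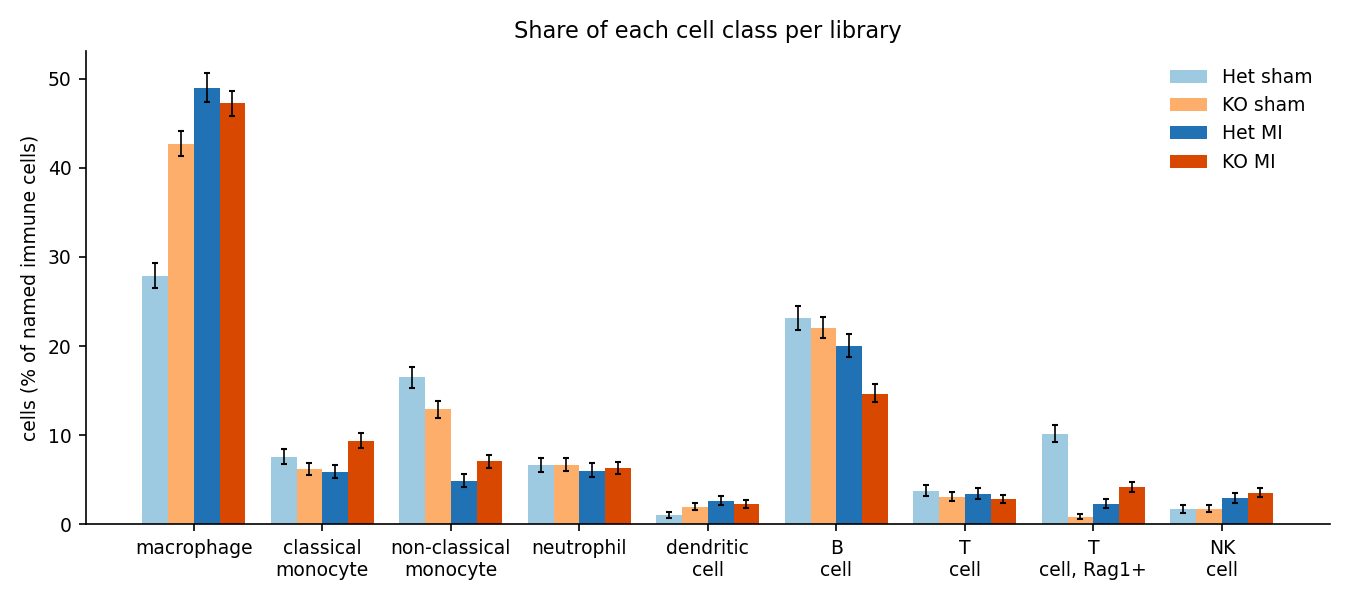
Share of each class in the named immune cells of each library, in percent, with exact Clopper-Pearson 95% intervals (counting error only, 1 library per group). Macrophages take 27.9% in Het_sham against 42.7%, 49.0% and 47.3% in KO_sham, Het_MI and KO_MI.

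Interferon-induced RNA set KO_MI macrophages apart from Het_MI macrophages. The interferon-gamma response list had a median log2 ratio of 0.78 [0.68 to 0.92] over 18 measured members, with 11 higher by at least 1.5-fold and 0 lower. The type I interferon list had a median of 0.93 [0.81 to 1.04] over 21 members, with 13 higher and 0 lower. MHC class II had a median of 1.31 [0.90 to 1.54] over 9 members and MHC class I, which presents peptides to CD8 T cells, one of 0.66 over 12. Each of these medians lay at percentile 100 of 10000 random lists matched on expression, which is a description of these libraries. As a scale shift, the median log2 ratio of all 10463 measured macrophage genes was −0.12, and TMM and median-of-ratios factors placed the centre at −0.11 and −0.12. Relative to that centre each macrophage ratio of this contrast is higher by the same amount.

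The genes behind those medians differed in level. Cxcl9, a chemokine induced by interferon-gamma that draws activated T cells, was at 36.5 CPM in KO_MI and 1.57 in Het_MI, a log2 ratio of 4.54 [4.05 to 5.08]. Gbp2, an interferon-induced GTPase, was at 63.2 and 7.70, a log2 ratio of 3.04. The more abundant Cxcl10 was lower in KO_MI (−0.31), as was Irf1 (−0.19), while Psmb9 was higher (0.66) and Irf8 nearly equal (0.12). Among type I genes, Ifi27l2a was higher (0.78), the abundant Bst2, Ifi204 and Isg15 were higher by 0.28, 0.34 and 0.16, Ifi44 was the highest (2.39, 41 against 8 UMIs) and Oas1a the lowest (0.13). Cd74, the invariant chain of MHC class II, was at 1474 and 511 CPM (1.53). H2-Aa, H2-Ab1 and H2-Eb1, the class II chains, were higher by 1.63, 1.57 and 1.58, and H2-Oa by 0.13. For class I, B2m was higher by 0.29, H2-D1 by 0.47, H2-K1 by 0.72 and Psmb8 by 0.78, with H2-Q7 the highest (1.52) and Tap2 the lowest (0.09).

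Part of this difference sat in a few clusters. A macrophage sub-cluster led by Cxcl9, Gbp2 and class II genes held 4.41% of KO_MI macrophages and 0.651% of Het_MI macrophages, 101 and 12 cells. Without this sub-cluster and the other myeloid cells clustered again with the dendritic cells, the interferon-gamma median was 0.63 and the class II median 0.83. Macrophages of the Spp1 and Gpnmb cluster, genes of phagocytes in injured tissue, made up 14.1% and 8.95%. The lipid-associated list as a whole had a median of 0.09 over 16 members.

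Alternative-activation and resident genes gave a mixed picture in the same cells. Retnla, a marker of alternative activation, was at 82.5 CPM in KO_MI and 4.15 in Het_MI (4.31), but 46.4% of its UMIs came from 1 cell, and without that cell the log2 ratio was 3.41. Arg1, an arginine-degrading enzyme of suppressive myeloid cells, was at 69.3 and 25.5 (1.44 [1.30 to 1.59]). The list of suppressive genes had a median of −0.16 over 15 members. The resident macrophage programme had a median of −0.43 [−0.46 to −0.39] over 12 members, at percentile 0, with 0 higher and 3 lower by at least 1.5-fold. Its member Lyve1, a hyaluronan receptor of vessel-associated macrophages, was at 91.2 and 150 CPM (−0.71), and Mrc1, F13a1, Stab1 and Maf had ratios of −0.42, −0.51, −0.47 and −0.34. The growth factor Igf1 was close to equal (−0.06). Further genes among the lowest were Ednrb (−0.86), the growth factor Bmp2 (−0.75) and the lysosomal enzyme Arsb (−0.72). Ctsk, a collagen-degrading protease, was lowest of all (−1.53), with 47.1% of its UMIs in 1 Het_MI cell and a ratio of −0.61 without it. The inflammatory and NF-kB list had a median of −0.26 over 17 members, with Cxcl2 at −0.14, Ccl4 at −0.41, Tnf at −0.42 and Ptgs2 at −0.67.

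**Figure D3:**
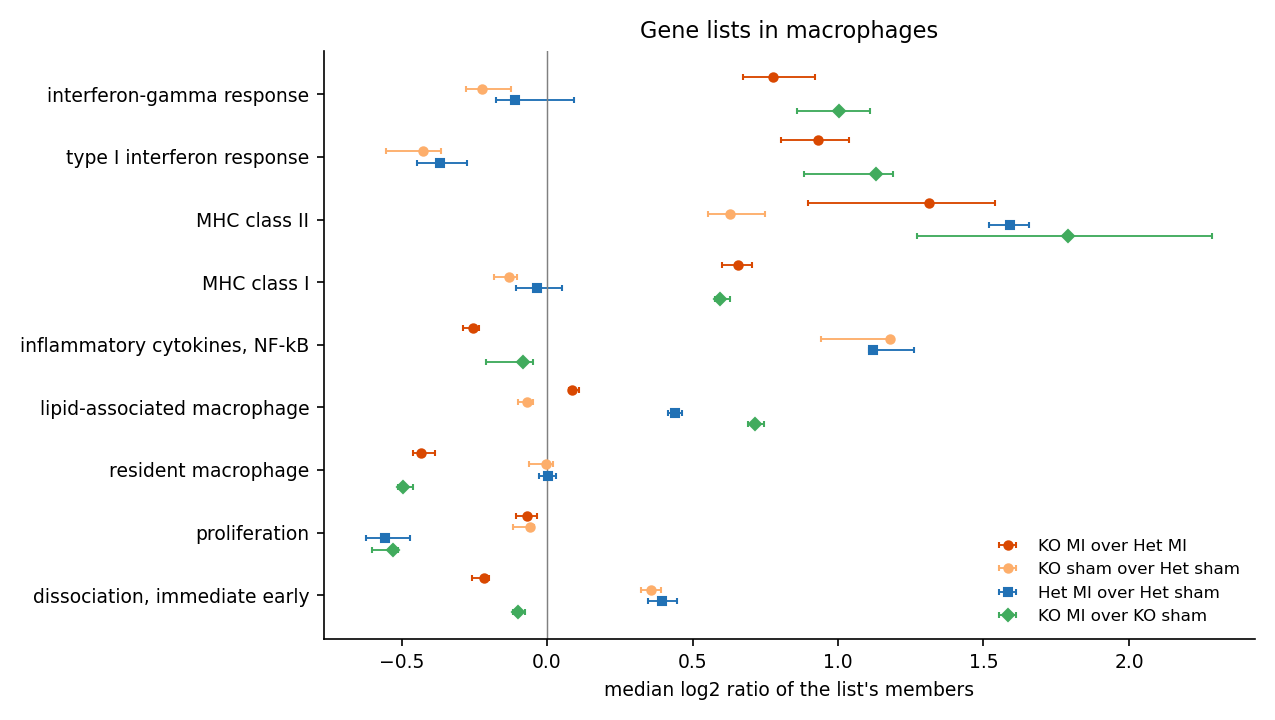
Median log2 ratio of the gene lists in macrophages for the contrasts, with intervals from counting error only (1 library per group). The MHC class II list stands at 1.31 for KO_MI over Het_MI and at 1.59 for Het_MI over Het_sham, and the inflammatory list at −0.26 and 1.12.

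Some RNA in the macrophage class belongs to other cells. Gzma, a granzyme of cytotoxic lymphocytes, was at 9.25 CPM in KO_MI macrophages and 1.01 in Het_MI macrophages (3.19). The cardiomyocyte list (0.08 over 8 members) and the fibroblast list (0.19 over 7) had intervals that include 0 and no member beyond 1.5-fold. Droplets with RNA of 2 lineages made up 20.3% of cells past the filter in KO_MI and 16.8% in Het_MI, and were removed.

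The sex of the animals also differed between these libraries. KO_MI held almost no Y-linked RNA, with a Y-linked UMI in 1 of 4843 named immune cells. In macrophages the Y-linked genes were at 80.1, 93.9, 129 and 0 CPM in Het_sham, KO_sham, Het_MI and KO_MI, and Xist, transcribed from the inactive X chromosome of females, at 324, 454, 255 and 1159. The sex-linked list is therefore set by the pool of animals, and so is Tsix, the antisense partner of Xist and the highest gene in B cells (2.08). Among macrophages with Xist and no Y-linked UMI in both libraries, the KO_MI over Het_MI medians were 0.67 for the interferon-gamma list, 1.56 for MHC class II, 0.62 for MHC class I and 0.38 for the type I list. The resident programme stood at −0.59 in these cells.

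**Figure D4:**
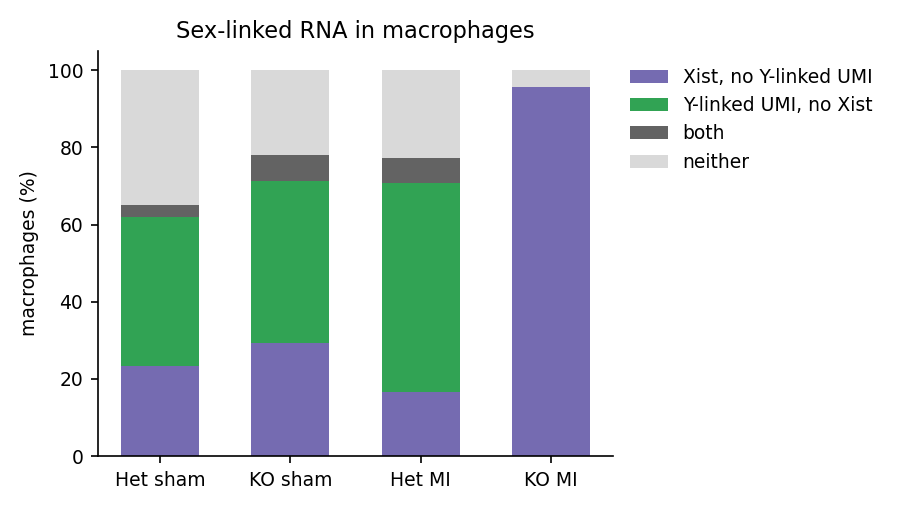
Share of macrophages in each library with Xist only, Y-linked RNA only (Ddx3y, Eif2s3y, Uty, Kdm5d), both or neither, in percent and without intervals. In KO_MI 95.5% held Xist only and 0% Y-linked RNA only, and the other libraries hold both kinds of cells.

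Monocytes showed a related difference. In classical monocytes the interferon-gamma list had a median of 0.75 over 17 members, with 12 higher and 0 lower, and MHC class I one of 0.71 over 12. Cxcl9 was at 505 and 92.3 CPM (2.45), with 72.7% of the Het_MI UMIs in 1 cell, so that the ratio is higher without that cell. Gbp2 was higher by 2.39 and Serpina3g, an interferon-induced protease inhibitor, by 3.51 [2.55 to 4.66]. Saa3, an acute-phase protein, was higher by 3.05, or 2.38 without the top cell. A sub-cluster of monocytes led by Cxcl9 held 13.7% of the class in KO_MI and 5.88% in Het_MI. Retnla went the other way, with 2 UMIs against 153 (−7.07 [−10.13 to −5.19]), but 97.4% of the Het_MI UMIs came from 1 cell, and the ratio without it was −1.81. Id3 was lower in classical (−1.21) and non-classical monocytes (−1.52). In non-classical monocytes the MHC class II list had a median of 1.99 over 6 members, Gbp2 was higher by 1.71, and Marco, a scavenger receptor, by 2.11, or 0.83 without the top cell. Lyz1 was lower (−3.17, and −2.15 without the top cell).

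Neutrophils of KO_MI carried more MHC class II RNA, with a median of 3.25 over 5 members and Cd74 at 347 against 31 UMIs. The same neutrophils carried more of the resident macrophage list (0.78 over 8 members) and of the efferocytosis and complement list (0.82 over 10), which are macrophage genes. Proliferation genes were higher too (1.42 over 8 members), and the inflammatory list was lower (−0.48 over 16). S100a4 was higher by 2.85 and Ms4a6c by 2.23 (1.60 without the top cell), while Il1rn, the interleukin-1 receptor antagonist, was lower (−1.33), as was Abtb2 (−1.28).

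The T cell class of KO_MI held more cytotoxic RNA, in part because it held more cells of a sub-cluster with T and NK genes, which could not be named by its own leading genes. In the whole class the effector list had a median of 0.78 [0.46 to 1.09] over 12 members, with 6 higher and 0 lower by at least 1.5-fold, at percentile 100. Ccl5, a chemokine of effector T cells, was at 4673 and 1630 CPM (1.52 [1.42 to 1.62]), Gzma was higher by 1.43 (0.98 without the top cell) and Nkg7 by 1.31. Ifng, the gene of interferon-gamma, had 47 UMIs in KO_MI and 8 in Het_MI (2.64), while Ccl4 was lower (−0.55). The naive T cell list had a median of −0.74 [−0.99 to −0.58] over 10 members, at percentile 0, with Satb1 at −1.25, Tcf7 at −1.09, Lef1 at −0.83 and Igfbp4 at −1.58. The type 17 list had a median of −1.22 over 5 members, and its cytokine gene Il17a had 12 UMIs against 51. Ly6a was higher by 1.72 (0.79 without the top cell), Lgals3 by 1.56 and Ybx3 by 1.47. Irf2bp2 (−1.36), Dusp10 (−1.34), Fam129a (−1.34), Tmem64 (−1.32) and Tshz1 (−1.27) were the lowest of the genes that met the naming rule. Different sub-clusters made up the class in the 2 libraries. The naive one held 11.1% of KO_MI and 27.3% of Het_MI T cells, the gamma-delta one 16.3% and 27.3%, and the one with NK genes 32.6% and 10.2%. Without the T cells of sub-clusters that could not be named, which left 83 cells in KO_MI and 106 in Het_MI, the effector median was 0.62, the naive median −0.51 and the type 17 median −0.87. Ccl5 then stood at 0.60, Ybx3 at 0.84 and Gzma at 3.21.

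In NK cells Gzmc was at 205 against 2 UMIs, 68.5-fold higher [18.7 to 569], with 31.2% of them in 1 of 21 cells (47.1-fold without it), and Gzmb was 2.83-fold higher. The NK effector list had a median of 0.42 over 17 members, of which 11 lay within 1.5-fold and 1, Eomes, was lower (−1.18). A dividing sub-cluster held 19.9% of the class in KO_MI and 11.8% in Het_MI. The naive list was lower (−1.09 over 7), with Ccr7, a lymph node homing receptor, at 3 against 55 UMIs (−4.78), and Cxcr4 was lower (−1.61). In B cells the type I interferon list had a median of 0.43 over 11 members. Jchain, a gene of antibody-secreting cells, was lower (−1.80), but 85.7% of the Het_MI UMIs came from 1 cell and the ratio without it was 1.01.

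The second comparison asks what infarction did in heterozygous mice. Macrophages took a larger and non-classical monocytes a smaller share in Het_MI than in Het_sham. Het_MI macrophages carried more Spp1 and Gpnmb RNA, more inflammatory and MHC class II RNA, and less RNA of the cell cycle. T cells showed more type 17 RNA.

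Macrophages made up 49.0% in Het_MI and 27.9% in Het_sham, a ratio of 1.76 [1.63 to 1.90]. Non-classical monocytes made up 4.89% and 16.5%, 3.37-fold lower [2.86 to 3.99], and classical monocytes 5.87% and 7.58%, a ratio of 0.775 [0.648 to 0.925]. NK cells had a ratio of 1.74 [1.27 to 2.40], which was 2.55 at resolution 0.5 and 2.71 at resolution 2.0. Dendritic cells had a ratio of 2.63 [1.79 to 3.91] and mast cells of 3.29 [1.73 to 6.70]. Type 2 innate lymphoid cells made up 1.04% and 0.305%. T cells with Rag1 made up 2.29% and 10.2%, and a large class such as this one changes every other share.

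Spp1, which encodes the secreted matrix protein osteopontin, was at 1410 CPM in Het_MI macrophages and 67.3 in Het_sham (4.39 [4.29 to 4.49]). Gpnmb was at 208 and 6.32 (5.04), the matrix gene Fn1 at 180 and 14.7 (3.62), and the elastase Mmp12 at 99.9 and 13.9 (2.85). Ctsk was the highest (6.56), at 54.8 and 0.582, and stayed at 5.64 without its top cell. The Spp1 and Gpnmb cluster held 8.95% of macrophages in Het_MI and 1.46% in Het_sham. The lipid-associated list had a median of 0.44 [0.42 to 0.47] over 16 members, with Apoe at 0.46, Ctsd at 0.48, Ctsb at 0.31 and Cd36 the lowest (−0.20). Growth factor and matrix genes had a median of 0.94 over 20 members, although the abundant Grn (0.03), Timp2 (0.10), Nrp1 (0.19) and Igf1 (0.21) were close to equal.

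Inflammatory and NF-kB genes had a median of 1.12 [1.11 to 1.26] over 17 members in macrophages, with 16 higher by at least 1.5-fold and 0 lower. Cxcl2, a chemokine for neutrophils, was at 8954 and 4145 CPM (1.11), Ccl4 was higher by 1.25, Tnf by 1.26, Nfkbia by 0.92, Ptgs2 by 2.51 and Sod2 by 0.15. The immediate early list, which cell dissociation also induces and which holds heat shock genes too, was higher in the same cells (0.40 over 16 members). Its members Junb and Egr1 stood at 1.02 and 1.18. MHC class II had a median of 1.59 over 9 members, with Cd74 at 1.59, H2-Aa at 2.95 and H2-Ab1 at 2.61. That median was 0.59 with only Scrublet calls removed, 0.66 in Xist-bearing cells, 0.73 without the myeloid cells clustered again with the dendritic cells, and 2.21 with every cell thinned to 2000 UMIs, so its size is uncertain. The type I interferon list went the other way (−0.37 over 20 members), with Rtp4 at −1.02, although Isg15 was higher, at 199.6 and 99.99 CPM. The interferon-gamma list stood at −0.11 over 17 members and the resident programme at 0.00 over 12. Neutrophil granule genes were higher in macrophages (1.30 over 7 members), with S100a9 at 1.30 and S100a8 at 1.48, and cardiomyocyte RNA was lower (−0.58 over 8 members). Inside Het_MI the granule list was lower in macrophages with Xist than in those with Y-linked RNA (−2.02 [−2.25 to −1.53]). These are genes of neutrophils, and the source of their RNA in the macrophage class was not tested.

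Proliferation genes were lower in Het_MI macrophages, with a median of −0.56 over 19 members, 9 lower and 0 higher by at least 1.5-fold. Tyms (−0.88), Birc5 (−0.88), Tk1 (−0.87), Gmnn (−0.84) and Ccna2 (−0.84), all genes of DNA synthesis or division, were the lowest of the class among genes that met the naming rule. The dividing cluster of macrophages held 14.8% of the class in Het_MI and 22.1% in Het_sham. The cluster led by Ccl4 and Cxcl2 held 40.1% and 17.8%.

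Among T cells of the same 2 libraries, the type 17 list had a median of 1.54 over 6 members, with Rora at 1.52, Cd163l1 at 1.55, Blk at 2.57 and Il17f at −1.50. Il17a stood at 68.3 CPM in Het_MI and 54.1 in Het_sham, from 51 and 50 UMIs, with 44.0% of the latter in 1 cell. The gamma-delta sub-cluster held 27.3% of T cells in Het_MI and 5.44% in Het_sham, and the naive one 27.3% and 46.9%. The activation list had a median of 0.56 over 11 members, with Maf, a transcription factor of type 17 and regulatory cells, at 2.04. Cdkn1a (2.37), Bcl2a1d (2.08), Klf4 (2.06) and Fam129a (1.73) were also among the highest. Klf2, which keeps naive T cells recirculating, was lower (−1.58), as were Igfbp4 (−1.40) and Mrpl21 (−1.31). Of the heat shock genes, 2 close relatives met the rule for the lowest genes in more than 1 class of Het_MI. The rule picks single genes, and no list of heat shock genes alone was measured. Both genes belong to the immediate early list, which cell dissociation also induces. Its median in T cells of Het_MI over Het_sham was 0.09, and −0.15 without those of unnamed sub-clusters. Hspa1a stood at −1.68 in T cells (−2.34 without those of unnamed sub-clusters), −1.90 in B cells, −1.94 in classical and −1.80 in non-classical monocytes, and Hspa1b at −1.33 in T cells and −2.31 in classical monocytes.

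Classical monocytes of Het_MI had 147 Arg1 UMIs against 1 in Het_sham (7.48 [4.98 to 12.79], and 6.88 without the top cell), and at least 69.5-fold more Cxcl9 (172 against 0 UMIs, set against 3 counts, lower limit 55.9-fold), with 72.7% of the Cxcl9 UMIs in 1 cell and a bound of 18.99-fold without it. Their inflammatory list had a median of 1.26 over 17 members, with Cxcl2 at 1.97 and Il1b at 1.08. In non-classical monocytes Gdf15 was higher by 1.23 and Apoc1 by 1.74 (0.13 without the top cell), and Marco was lower (−2.22), although it was higher (1.98) with only Scrublet calls removed. Neutrophils had more Spp1 (1.79) and Clec5a (1.56) and less Atf3 (−1.63) and Slc20a1 (−1.51), and their immediate early list was lower (−0.58 over 16 members). In B cells Jchain was higher (1.95), which the single Het_MI cell with 85.7% of its UMIs set, since the ratio without it was −0.85.

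The third comparison asks the same of infarction in KO mice. KO_MI macrophages shared with Het_MI macrophages the higher Spp1 and Gpnmb and the lower cell cycle genes relative to their own sham library. They had higher interferon RNA, and their inflammatory genes were level with KO_sham. Classical monocytes took a larger and non-classical monocytes a smaller share than in KO_sham.

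Macrophages had a share ratio of 1.11 [1.04 to 1.17] for KO_MI over KO_sham, classical monocytes of 1.52 [1.31 to 1.76], non-classical monocytes of 0.547 [0.478 to 0.625] and NK cells of 2.02 [1.55 to 2.66]. The macrophages sat in different clusters, with 14.1% of KO_MI and 1.35% of KO_sham macrophages in the Spp1 and Gpnmb cluster. The dividing cluster held 13.2% and 22.7%, and the Cxcl9 sub-cluster 4.41% and 0.0962%. In macrophages Arg1 had 1469 UMIs against 7 (7.92 [6.87 to 9.24]), Spp1 was higher by 5.30 and Gpnmb by 4.45. The type I list had a median of 1.13 over 21 members, the interferon-gamma list one of 1.005 over 18, with Cxcl9 at 4.99 and Cxcl10 at −0.47, and MHC class II of 1.79 over 9, with H2-Aa at 3.08. The lipid-associated list stood at 0.71 over 16 members, with Apoe at 0.61, and the inflammatory list at −0.08 over 17. The resident programme was lower (−0.50 over 12), with Lyve1 at −1.13 and Stab1 at −0.59. The proliferation list was lower as well (−0.53 over 19), as were the histone gene Hist1h1b (−0.94) and Npl (−0.90). Fibroblast RNA was higher (0.47 over 7 members). The median of all macrophage genes was −0.13 here. T cells had less naive RNA (−0.96 over 10 members, 9 lower by at least 1.5-fold). Ly6a (1.99, and 1.07 without its top cell), the chemokine Xcl1 (1.70, but −0.83 without the T cells of unnamed sub-clusters) and Cd163l1 (1.40) were the highest, and Cmah (−1.71), Kif1b (−1.69) and Txnip (−1.43) the lowest. Across 11377 genes the macrophage log2 ratios for MI in Het and in KO had a Pearson r of 0.432 and a Spearman rho of 0.325. Genes are not independent replicates.

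The fourth comparison asks what loss of PD1 did without infarction. The Rag1-bearing T cells, a large class in Het_sham, were nearly missing from KO_sham, which by itself raises every other share. KO_sham also had a larger share of macrophages and dendritic cells, and its macrophages had more inflammatory and less interferon RNA.

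Macrophages made up 42.7% in KO_sham and 27.9% in Het_sham, a ratio of 1.53 [1.42 to 1.65]. Dendritic cells had a ratio of 1.92, classical monocytes of 0.815 and non-classical monocytes of 0.781. T cells with Rag1 made up 0.842% and 10.2%, a ratio of 0.0829 [0.0586 to 0.115]. In macrophages the inflammatory list had a median of 1.18 over 17 members, with 15 higher by at least 1.5-fold and 0 lower. The class sat in different clusters in these libraries, with 38.7% of KO_sham and 17.8% of Het_sham macrophages in the cluster led by Ccl4 and Cxcl2, and the mean of the inflammatory medians inside 5 single clusters was 0.49. Ptgs2, which makes prostaglandins, was at 54.3 and 15.6 CPM (1.80), the neutrophil chemokine Cxcl1 at 635 and 207 (1.62) and Il1a was higher by 1.55. No gene met the rule for the lowest. The immediate early list stood at 0.36, MHC class II at 0.63, the interferon-gamma list at −0.22 and the type I list at −0.43, with Irf7 at 11.0 and 22.0 CPM and Isg15 higher by 0.98. In T cells Rora (1.10) and Icos (1.06) were higher, Hspa1b was lower (−1.58), and Ly6a was lower (−1.57, and −0.15 without its top cell). The log2 ratios for KO in sham and after MI had a Pearson r of −0.115 and a Spearman rho of −0.155 across 11377 macrophage genes.

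The last comparison asks whether loss of PD1 did something after infarction that it did not do in sham hearts, as KO_MI over Het_MI divided by KO_sham over Het_sham. The macrophage share had a ratio of ratios of 0.630, classical monocytes of 1.958, non-classical monocytes of 1.84 and mast cells of 0.275. In macrophages Retnla (4.21), Gbp2 (3.29) and Arg1 (2.25) were the highest. Without the cell with the most UMIs in each library Retnla stood at −0.74, so single cells set its value, while Gbp2 and Arg1 stood at 3.34 and 2.17. Gbp2 stood at 8.40, 7.07, 7.70 and 63.2 CPM in Het_sham, KO_sham, Het_MI and KO_MI. Ctsk (−2.34), Il1a (−1.92) and Cxcl1 (−1.88) were the lowest, and Cxcl1 stood at 207, 635, 634 and 531. In T cells Xcl1 (3.57), Ifng (3.56) and Ly6a (3.28) were the highest. Ly6a had 47.3% of its KO_MI and 62.6% of its Het_sham UMIs in 1 cell each, and stood at 1.77 without the cell with the most UMIs in each library. Xcl1 had 59.3% of its KO_sham UMIs in 1 cell, and stood at 4.94 by the same measure but at 1.33 without the T cells of unnamed sub-clusters, so its place rests largely on those cells. Ifng stood at 88.7, 46.8, 10.7 and 66.8, so its ratio rests mainly on the low Het_MI value, and KO_MI lay below Het_sham. Il17a (−2.50), Zbtb20 (−2.49) and Acsl4 (−2.38) were the lowest.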

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

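The tests of dissociation, of sex in the MHC class II and type I lists, of thymus cells, of genotype and of macrophage clusters in KO_sham were chosen after the results were seen, and the others before. None of the differences between groups listed here was tested, since each group has 1 library. They stand out because the direction was opposite in the groups compared.

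T cells with Rag1 were 0.0829 times as frequent in KO_sham as in Het_sham and 1.825 times as frequent in KO_MI as in Het_MI. By surgery, the ratio of MI over sham was 0.225 in Het and 4.95 in KO. In Het_sham, KO_sham, Het_MI and KO_MI these cells held Rag1, a gene of developing thymocytes, at 403, 505, 441 and 302 CPM. Tcf7 stood at 695, 742, 574 and 574 CPM in them. It was also counted at 424, 294, 372.5 and 175 CPM in the T cell class, so it does not mark thymocytes alone.

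Whether genotype moves the Rag1-bearing share is open, because the opposite ratios of 0.0829 in sham and 1.825 after MI rest on 1 library per group, where genotype and pool cannot be told apart. A candidate explanation is thymus tissue carried over with the heart, which a sort on CD45 does not remove, since thymocytes carry CD45. Carry-over predicts 1 mix of thymocyte stages in every library only if the thymus held the same mix in each pool, which was not measured. The stage ratios therefore cannot decide on carry-over. They were taken against the Rag1 and Cd8 sub-clusters, of which 1 is itself led by histone genes. The early sub-cluster had a ratio spread of 1.63-fold between libraries, but a dividing one (0.393, 0.0938, 0.346 and 0.647) had a spread of 6.90-fold. The latter goes against 1 mix, yet it rests on 3 KO_sham cells, with intervals that allow 1.56-fold and a spread of 1.87-fold among the other libraries. Handling of the animals in each pool remains untested.

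Interferon and MHC RNA was higher in KO_MI than in Het_MI macrophages. A stronger dissociation response does not account for it, with the immediate early list at −0.22. With every cell thinned to the same UMIs the interferon-gamma median was 0.725, so its value does not rest on the deeper cells. That cannot test depth itself, because CPM of summed UMIs does not scale with depth, and it covers this list alone. KO_MI had almost no Y-linked RNA, so sex was tested too. In Het_MI, macrophages with Xist differed from those with Y-linked RNA by 0.003 [−0.128 to 0.138] on the interferon-gamma list. That difference was −0.112 in Het_sham and −0.012 in KO_sham. These values argue against sex for that list. Their intervals cover counting error only, so differences between the animals of each sex are not covered. On the class II list the same difference was −0.61 in Het_MI but 1.16 in Het_sham and 0.56 in KO_sham. Without a constant sign, sex is not excluded for class II. Among Xist-bearing cells alone the class II median of KO_MI over Het_MI was 1.56, which argues against the sex mix alone as its source. For the type I list, sex and genotype cannot be told apart, because that restriction left a median of 0.38 with an upper bound of 0.585, from below to above 0.5 times the main value, and inside single libraries macrophages with Xist differed from those with Y-linked RNA by 0.438 [0.329 to 0.587] in Het_MI and 0.221 in Het_sham but by −0.290 [−0.376 to −0.171] in KO_sham. Genotype stays a hypothesis, with the pool of animals and the library as open alternatives.

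Inflammatory RNA was lowest in Het_sham macrophages, the common reference of the higher values in KO_sham and Het_MI. Dissociation acting on all cells alike is argued against, since the immediate early list was higher than in Het_sham in only 1 of the 5 other classes, in Het_MI and in KO_sham alike. Another mix of macrophage clusters is argued against as the whole account for Het_MI, because the mean over 5 clusters of the inflammatory median inside the cluster was 0.84 (SE over clusters 0.147) against 1.12 in the whole class. For KO_sham it stays open, because that mean was 0.494 (SE 0.163) against 1.18, a range from below to above 0.5 times the class value. Both means weight the 5 clusters alike and leave out the Spp1 and Gpnmb cluster, which held few Het_sham cells. The cluster led by Ccl4, Cxcl2, Cxcl1 and Tnf took a larger share in Het_MI and KO_sham than in Het_sham. Those genes belong to the inflammatory list, so the share of that cluster is not a separate measure from inflammatory RNA. The clusters share the same libraries, so the SE is not a spread between animals. A response of macrophages alone to handling, which differs between hearts, was not tested.

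Classical monocytes were 0.815 times as frequent in KO_sham as in Het_sham and 1.60 times in KO_MI as in Het_MI. Their ratio of MI over sham was 0.775 in Het and 1.52 in KO. Non-classical monocytes had KO over Het ratios of 0.781 in sham and 1.44 after MI. In neutrophils the efferocytosis and complement list was higher after MI in Het (0.68) and lower in KO (−0.71), but each sign depends on the processing, with −0.092 in Het as a mean over cells, and 0.58 with doublets kept and 0.404 with only Scrublet calls removed in KO. In B cells the sex-linked list was higher after MI in Het (0.66) and lower in KO (−3.74), which goes with the sex mix of the libraries.

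A cluster that could not be named, led by Marco, Saa3, Arg1 and Retnla, held 0, 0, 4 and 64 cells in Het_sham, KO_sham, Het_MI and KO_MI, or 1.17% of kept KO_MI cells. It stands out because no comparison of classes uses it, and a cluster mostly of 1 library is not shown to be a cell type.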

How the results depend on the processing

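Settings based on sex, on Scrublet calls alone, on the Cxcl9 clusters, on Rag1-bearing cells, on unnamed T cell sub-clusters and on thinning or doublets in lists were chosen after seeing the data, and the others before. No paired analysis was possible because each group has 1 library, numbered 1. The causes of the changes given here were not tested, except where a setting states them.

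A value counts as reversed only where its direction changed and the main value was clear. Clear means a share interval that excluded equal shares, a gene interval beyond 1.5-fold or a list median of at least 1.5-fold. Other changes of direction count as kept or moved. Class share ratios kept within the interval of the main value in 442 of 472 recomputed values, moved beyond it in 30 and reversed in 0. Gene folds did so in 809, 223 and 2 of 1034, and list medians in 3195, 969 and 7 of 4171. Intervals of abundant genes and lists are narrow, so small moves leave them.

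The NK ratio of Het_MI over Het_sham (1.74) was 2.55 at resolution 0.5, 2.71 at resolution 2.0 and 2.46 with only Scrublet calls removed. Under that last setting the T cell ratio of KO_MI over Het_MI (0.819) was 1.05, while it was 0.611 without the T cells of unnamed sub-clusters, and for Het_MI over Het_sham the macrophage ratio (1.76) was 1.62 and the non-classical monocyte ratio (0.297) was 0.381. Without Rag1-bearing T cells the macrophage ratio was also 1.62. With at most 5% mitochondrial UMIs the macrophage ratio of KO_MI over Het_MI (0.965) was 0.903.

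Pdcd1 in T cells was 6.94 CPM in Het_sham when thinned. With doublets kept it was 5.77, 10.3 and 31.6 CPM in KO_sham, Het_MI and KO_MI, and with only Scrublet calls removed 11.2 and 35.2 in the MI libraries.

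For KO_MI over Het_MI in macrophages, the interferon-gamma median (0.78) was 0.64 over members at 10% or more of the highest class, 0.63 without the Cxcl9 clusters (the myeloid cells clustered again with the dendritic cells) and 0.67 in Xist-bearing cells. MHC class II (1.31) was 0.83 without those clusters and 1.56 in Xist-bearing cells. The lipid-associated list (0.09) was 0.199 with TMM, 0.203 with median of ratios, 0.11 thinned, 0.13 without those clusters and 0.504 in Xist-bearing cells.

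For Het_MI over Het_sham in macrophages, the interferon-gamma median (−0.11) was 0.24 with doublets kept, 0.16 with only Scrublet calls removed, −0.29 thinned, 0.18 in Xist-bearing and −0.18 in Y-bearing cells, so its sign is open. MHC class II (1.59) was 1.66 with TMM, 1.43 as a mean over cells, 0.59 with only Scrublet calls removed, 2.21 thinned, 0.73 without the Cxcl9 clusters, 0.66 in Xist-bearing and 1.32 in Y-bearing cells. The lipid-associated list (0.44) was 0.51 with TMM, 0.499 with median of ratios, 0.37 as a mean over cells, 0.35 thinned and 0.31 in Xist-bearing cells.

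Reversals were few. With only Scrublet calls removed, Marco in non-classical monocytes of Het_MI over Het_sham went from −2.22 to 1.98, and MHC class II in classical monocytes from 1.44 to −0.055. Without the T cells of unnamed sub-clusters, Xcl1 in T cells of KO_MI over KO_sham went from 1.70 to −0.827. As a mean over cells, the effector list in macrophages of Het_MI over Het_sham went to −0.069, the efferocytosis list in neutrophils to −0.092, and MHC class II in classical monocytes of KO_sham over Het_sham to −0.051. In neutrophils of KO_MI over KO_sham, the resident list went to 0.12 and the efferocytosis list to 0.58 with doublets kept, and the latter to 0.404 with only Scrublet calls removed.

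The correlation of the MI log2 ratios in Het and KO macrophages (0.432) was 0.334 with genes of at least 30 UMIs and 0.451 without haemoglobin, sex-linked, ribosomal, mitochondrial and immediate early genes. The thinned class II median for Het_MI over Het_sham rests on 6 members against 9.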

Other observations

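The values here were looked at after the results were seen. Droplets with RNA of a macrophage and a T cell marker set made up 8.87%, 4.45%, 7.51% and 12.2% of the cells past the filter in Het_sham, KO_sham, Het_MI and KO_MI. Rag1, which macrophages do not express, stood at 8.57, 0.572, 2.08 and 3.82 CPM in macrophages of the same libraries, in the order of the shares of Rag1-bearing T cells (10.2%, 0.842%, 2.29% and 4.17%).

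A cluster led by cardiomyocyte genes with macrophage markers stayed unnamed and held 85, 119, 53 and 71 cells in the same order. Migratory dendritic cells, led by Ccr7, Ccl22 and Fscn1, numbered 2, 11, 19 and 39. Within single libraries, macrophages with Xist differed from those with Y-linked RNA on the MHC class II list by 1.16 in Het_sham, 0.56 in KO_sham and −0.61 in Het_MI, so the sign was not the same in the 3 libraries that hold both sexes.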
